A study of Homo sapiens with 6 samples.

How the data were processed

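The series holds 6 small RNA libraries of A549 cells, 3 from cells transfected with empty pcDNA4 and 3 from cells transfected with pcDNA4 carrying SMARCA4. Per the labels' protocols, plasmids were delivered with a lipid reagent, RNA was taken at 48 h with a kit that keeps small RNA, and libraries were made with a TruSeq small RNA kit. Per the submitters' processing notes, base calls were converted with bcl2fastq 2.18.0.12 and the genome build was GRCh38. The adapter trimmer, aligner, counting program, miRNA annotation and the treatment of reads that match several miRNAs are not given in the sources used here. Such a kit ligates adapters to RNA ends, and ligation efficiency differs between miRNAs, so values compare 1 miRNA between libraries better than different miRNAs within a library. No molecular identifiers are mentioned in the labels.

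The values the authors deposited are a normalized signal per mature miRNA, a read count multiplied by 1 factor per library, and the name of the deposited table speaks of TMM, a trimmed mean of log ratios between libraries. In each library every value was a whole multiple of the smallest step, within a tolerance of 1e-06 reads, so the read counts were recovered for 100% of the values. The value of 1 read ranged from 0.422 in SMARCA4 replicate 2 to 2.61 in SMARCA4 replicate 1. The geometric mean of the deposited totals and the mean recovered total were both 1939848.5, and the deposited totals ranged from 1661870 to 3073322. The recovered totals cover reads assigned to listed miRNAs, and total sequencing depth was not analysed here. A count of 0 allows up to 3 reads, which corresponds to 1.27 normalized counts in SMARCA4 replicate 2 and to between 4.91 and 7.84 in the other libraries. That limit covers counting error only, since amplified reads are not independent molecules.

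Groups and replicate numbers were taken from sample titles. The design text calls the replicates independent biological replicates. No pair of libraries agreed within sampling noise. The lowest chi-square per degree of freedom was 7.72, between SMARCA4 replicates 1 and 3. Pearson correlations of log2 values ranged from 0.955 to 0.969 within the empty vector group, from 0.937 to 0.966 within the SMARCA4 group and from 0.911 to 0.950 between groups. The labels give no sequencing batch or date.

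The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with an empirical Bayes mean-variance trend and the group as the only term, over the 637 miRNAs with a mean value of at least 1 over all 6 libraries. The other 150 were not tested. Adjusted p-values follow Benjamini and Hochberg, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of scarce miRNAs. This design, the processing alternatives, the lists and the rule for named miRNAs were fixed before the data were examined. The design had assumed a normalized unit and kept its test. As alternatives, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads, where DESeq2 left 237 adjusted p-values undefined. Single values such as shares and ratios were compared with exact two-sided permutation tests, which with 3 against 3 libraries cannot go under 0.1.

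A total of 18 lists of miRNAs were fixed, and 17 had the 3 measured members required for a test. They were tested with camera (preset correlation 0.01), with camera using an estimated correlation, and with fry, which asks whether the members move one way on balance without setting them against other miRNAs. fry passed 3 lists, which were the immune-response, miR-30 and miR-221/222 lists. p-values were adjusted over the 17 lists. The lists overlapped in miR-9-5p (immune-response and neuron lists) and miR-143-3p (p53 and mesenchymal lists). Arms were paired by hairpin name, and the relation of their changes was tested with 100000 permutations of the pairing.

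Named miRNAs followed a fixed rule. It took all arms of miR-221 and miR-222, up to 10 changed miRNAs per direction by size of change with no overlap of the groups and a mean of at least 10, further miRNAs by smallest unadjusted p up to 6 per direction given as values that did not pass, the 5 most abundant miRNAs, and the 2 most abundant and any changed members of each list. The third part was read as filling each direction to at most 10, with at most 6 such miRNAs. Any other miRNA named was chosen after its values were seen.

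Hairpin positions, host genes and sequences come from GENCODE 29 on GRCh38, and 774 of the 787 names were placed on an annotated hairpin gene. The deposited table holds no coordinates, and the annotation release the authors used is not given in the sources used here. Positions of the 4 arms of miR-221 and miR-222 were found by matching their known sequences to the hairpins.

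The alternatives were a pseudocount of 0.5 or 5, no filter, a mean of at least 10, libraries rescaled to the same total, median-of-ratios scaling, quantile normalization, limma without the trend or with array weights, edgeR, DESeq2, the replicate number as a block, other list tests, and each library left out in turn. A version with SMARCA4 replicate 2 thinned to 872952 reads and an arm filter at a mean of at least 100 were added after seeing the data. The main test was checked on simulated counts for this comparison, with 637 miRNAs, 200 of them changed, 3 libraries per group and 10 runs. Among simulated miRNAs with a mean of at least 10, it called 20.8% of those changed 2-fold, 75.4% of those changed 4-fold, 94.4% of those changed 8-fold. Of all unchanged miRNAs it called 0.732%. The Benjamini-Hochberg cutoff is more lenient the more miRNAs change. Where fewer than 200 change, these shares of changed miRNAs called can be too high.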

Results

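Small RNA libraries were compared between A549 cells that had received the empty plasmid pcDNA4 and A549 cells that had received pcDNA4 carrying SMARCA4, 48 h after transfection. A549 is an established human lung adenocarcinoma line of epithelial origin. SMARCA4, also called BRG1, is one of the alternative ATPases of the SWI/SNF chromatin remodelling complex, and the labels describe the transfection as a restoration of its expression. Each group held 3 libraries, which the design text describes as independent biological replicates. The deposited table listed normalized read counts for 787 mature miRNAs, of which 44 were at 0 in every library. The recovered read totals were 881370, 933753 and 1079944 in empty vector replicates 1, 2 and 3, and 701885, 7274329 and 767810 in SMARCA4 replicates 1, 2 and 3. SMARCA4 replicate 2 therefore held 8.33 times the mean read total of the other 5 libraries. SMARCA4 mRNA was not analysed here, so the group labels were not checked against the level of the gene itself.

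The study's title describes miR-222 as a tumor suppressor in lung adenocarcinoma whose expression SWI/SNF regulates, and gives no direction. The labels do not say whether a fall or a rise with SMARCA4 was anticipated. Both arms of miR-222 fell with SMARCA4. miR-222-3p was at 22393 ± 1893 normalized counts (SD, n = 3) in empty vector cells and at 7575 ± 791 (SD, n = 3) in SMARCA4 cells, which is 2.96-fold lower (log2 fold change −1.57, SE 0.24, limma adjusted p = 0.0124). miR-222-5p, the less abundant arm of the same hairpin, went from 265 ± 39.4 to 50.1 ± 9.06 (SD, n = 3 each), which is 5.21-fold lower (log2 fold change −2.38, SE 0.32, limma adjusted p = 0.0119). The neighbouring miR-221 did not pass the test on either arm. Its 3p arm was higher with SMARCA4, at 7055 ± 973 against 15593 ± 7115 (SD, n = 3 each; log2 fold change 1.06, SE 0.34, limma adjusted p = 0.110), and its 5p arm was lower, at 843 ± 417 against 198 ± 57.2 (SD, n = 3 each; log2 fold change −2.00, SE 0.44, limma adjusted p = 0.0656). For each of the 4 arms the groups of 3 did not overlap, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows. With any 1 library left out the log2 fold change stayed between −1.65 and −1.51 for miR-222-3p and between −2.52 and −2.27 for miR-222-5p, but both calls were lost without any of 4 libraries. The adjusted p of miR-222-3p was 0.103, 0.0991, 0.0933 and 0.0853 without empty vector replicate 1, empty vector replicate 3, SMARCA4 replicate 1 and SMARCA4 replicate 3, and that of miR-222-5p was 0.0662, 0.0635, 0.0508 and 0.0853 without the same libraries. Without the mean-variance trend of limma the adjusted p of miR-222-3p was 0.0695. miR-221-5p passed at 0.0249 without empty vector replicate 2 and at 0.0462 without SMARCA4 replicate 2.

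**Figure D1:**
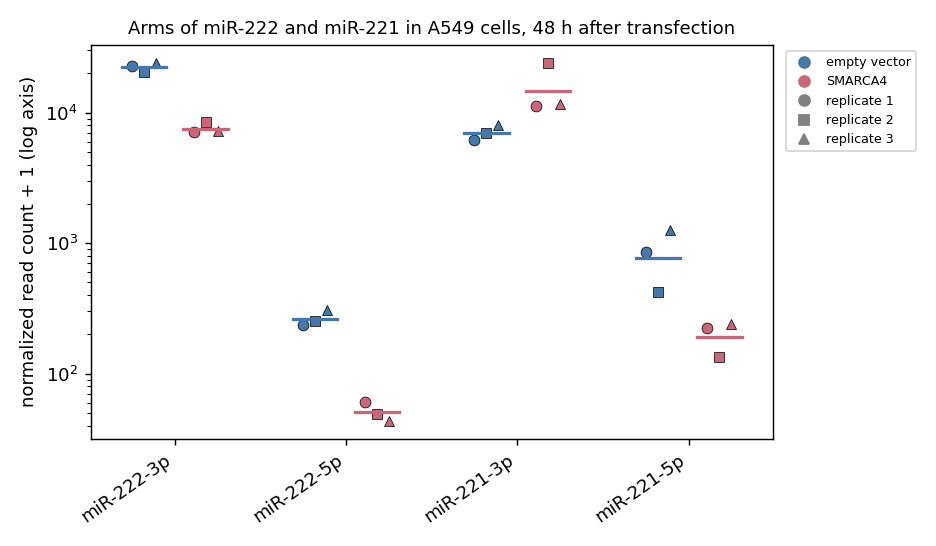
Normalized read count plus 1 (log axis) of the arms of miR-222 and miR-221 in each library; points are libraries, shapes are replicates and lines are geometric means of 3 libraries. The SMARCA4 libraries lie under all empty vector libraries for miR-222-3p, miR-222-5p and miR-221-5p and above them for miR-221-3p.

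Both hairpins lie on the minus strand of chromosome X in GRCh38 (GENCODE 29), in an intron of the lincRNA gene MIR222HG (45745211 to 45770274). MIR221 spans 45746157 to 45746266 and MIR222 spans 45747015 to 45747124, with 748 bases between them. miR-222-3p (AGCTACATCTGGCTACTGGGT, DNA letters) was placed at 45747036 to 45747056 and miR-222-5p (CTCAGTAGCCAGTGTAGATCCT) at 45747073 to 45747094. miR-221-3p (AGCTACATTGTCTGCTGGGTTTC) was placed at 45746180 to 45746202 and miR-221-5p (ACCTGGCATACAATGTAGATTT) at 45746221 to 45746242. The 3p arms of miR-221 and miR-222 share their first 8 bases, which include the seed, and differ by 6 edits over their full lengths when gaps are allowed, or by 3 when the last bases of miR-221-3p are not counted.

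Over the 637 miRNAs tested, 9 changed with SMARCA4, of which 6 rose and 3 fell (limma, adjusted p under 0.05), and 144 had an unadjusted p under 0.05. The largest rises were of miR-3609, 27.9-fold (log2 fold change 4.80, SE 0.73, adjusted p = 0.0124), and miR-3614-5p, 18.0-fold (log2 fold change 4.17, SE 0.55, adjusted p = 0.0119). Both were scarce in empty vector cells: miR-3609 had 0, 1 and 4 reads there against 79.5 ± 25.6 normalized counts with SMARCA4, and miR-3614-5p had 11 reads over the 3 empty vector libraries against 142 ± 87.4 normalized counts with SMARCA4 (SD, n = 3 each). Their sizes and order depend on these few reads. The log2 fold change of miR-3609 was 3.48 with a pseudocount of 5, 4.06 without empty vector replicate 1 and 5.52 without empty vector replicate 3, and that of miR-3614-5p was 3.55 with a pseudocount of 5. miR-203a-3p, an epithelial miRNA that is abundant in skin, rose from 4.79 ± 0.972 to 39.7 ± 2.97 (log2 fold change 2.83, and 2.19 with a pseudocount of 5; adjusted p = 0.0124). miR-141-3p, a member of the miR-200 family that restrains the epithelial to mesenchymal transition, rose 5.86-fold, from 31.4 ± 10.8 to 182 ± 30.3 (adjusted p = 0.0124). miR-424-3p rose 3.52-fold, from 299 ± 34.2 to 1074 ± 278 (adjusted p = 0.0124), and miR-181c-5p rose 2.75-fold, from 647 ± 196 to 1732 ± 103 (adjusted p = 0.0456). Beside the arms of miR-222, miR-654-3p of the imprinted 14q32 cluster fell 3.93-fold, from 1101 ± 357 to 271 ± 38.7 (adjusted p = 0.0128; SD, n = 3 throughout).

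**Figure D2:**
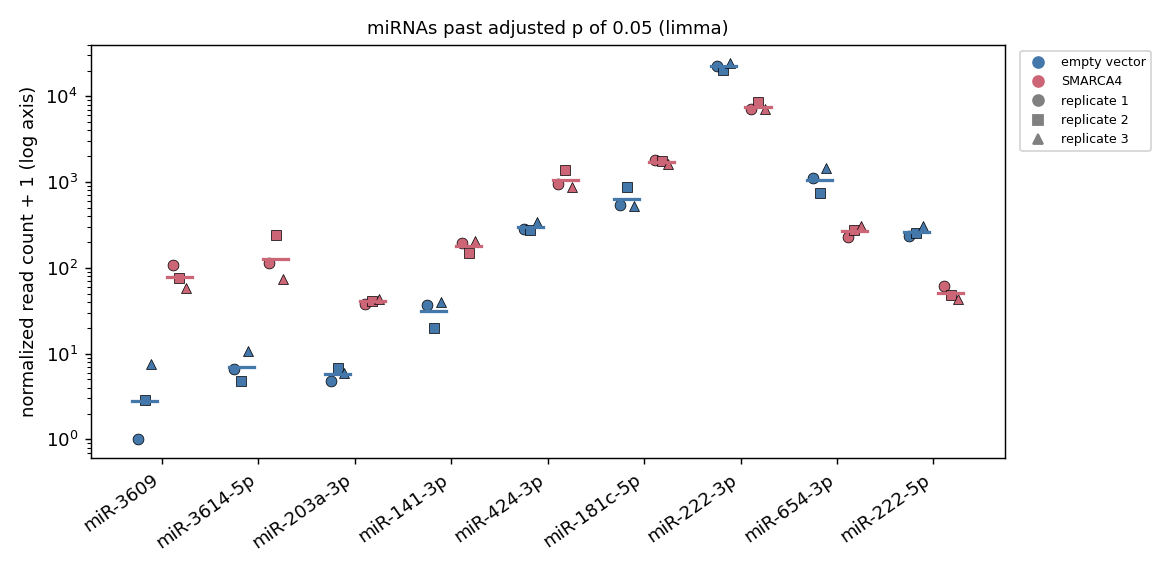
Normalized read count plus 1 (log axis) in each library for the 9 miRNAs past an adjusted p of 0.05; points are libraries, shapes are replicates and lines are geometric means of 3 libraries. The groups do not overlap for any of the 9, and miR-3609 and miR-3614-5p start from 0 to 6 reads per empty vector library.

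Several of these hairpins lie inside genes. MIR3609 (chromosome 7, 98881650 to 98881729) lies in an intron of TRRAP, MIR141 (chromosome 12, 6964097 to 6964191) in an intron of the lincRNA gene MIR200CHG, and MIR181C (chromosome 19, 13874699 to 13874808) in an intron of NANOS3, each on the same strand. MIR3614 (chromosome 17, 56891270 to 56891355) lies in a UTR of TRIM25, a ubiquitin ligase of antiviral signalling, on the same strand. The hairpins of miR-203a, miR-654 and miR-424 lay inside no other gene annotated in GENCODE 29. MIR203A (chromosome 14, 104117405 to 104117514) overlapped the hairpin gene MIR203B on the opposite strand, MIR424 (chromosome X, 134546614 to 134546711) overlapped the lincRNA gene MIR503HG on the same strand by 19 bases, and MIR654 (chromosome 14, 101040219 to 101040299) overlapped none.

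All 9 changes kept their direction when any single library was left out, but the number of calls varied with the library left out. It was 0 without empty vector replicate 1, 12 without empty vector replicate 2, 2 without empty vector replicate 3, 0 without SMARCA4 replicate 1, 41 without SMARCA4 replicate 2 and 1 without SMARCA4 replicate 3, where the unadjusted counts were 103, 133, 113, 119, 167 and 127. All 9 passed without empty vector replicate 2 or SMARCA4 replicate 2. Those of the 9 that missed the threshold had adjusted p-values from 0.0662 to 0.189 without empty vector replicate 1, from 0.0547 to 0.155 without empty vector replicate 3, from 0.0508 to 0.123 without SMARCA4 replicate 1 and from 0.0853 to 0.143 without SMARCA4 replicate 3. miR-3614-5p passed in 4 of the 6 settings, miR-3609 in 3 and the others in 2. miR-181c-5p also missed the threshold with libraries rescaled to the same total (0.0925), with quantile normalization (0.0913), without the trend (0.0999) and by edgeR (0.0509), miR-141-3p with the same total (0.0519), and miR-424-3p and miR-654-3p without the trend (0.0562 each). On the recovered reads, edgeR called 8 miRNAs (5 rose, 3 fell), all among the 9, and DESeq2 called 47 (24 rose, 23 fell), with all 9 among them. With libraries rescaled to the same total 12 were called, of which 4 rose and 8 fell. That scaling moved the median log2 fold change of all tested miRNAs by −0.26, and the cause of the different counts was not tested. The groups did not overlap for 198 miRNAs, 31.1% of those tested, where 10% is expected by chance for a single miRNA. miRNAs measured in the same libraries are not independent, so this share is not a test of the group difference.

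Further miRNAs had large differences that did not pass the test, all with a limma adjusted p of 0.0656 and no overlap of the groups. On the higher side with SMARCA4, miR-181a-5p was at 20264 ± 9985 against 63130 ± 23020, miR-10b-5p at 11347 ± 2503 against 26564 ± 6429, miR-324-3p at 28.4 ± 3.34 against 100 ± 33.5 and miR-431-3p at 22.0 ± 9.33 against 87.7 ± 23.9 (SD, n = 3 each). On the lower side, miR-30c-5p was at 8038 ± 1287 against 3112 ± 1050, miR-1303 at 65.7 ± 16.1 against 18.9 ± 2.89, miR-411-3p at 36.8 ± 6.05 against 8.52 ± 1.74, miR-191-3p at 33.6 ± 4.02 against 3.32 ± 3.89 and miR-337-3p at 21.9 ± 7.70 against 2.87 ± 1.74 (SD, n = 3 each). The SMARCA4 means of miR-191-3p and miR-337-3p lie under the value of 3 reads in SMARCA4 replicates 1 and 3 (7.84 and 7.08). The sizes of both differences therefore rest on few reads.

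Of 17 fixed lists of related miRNAs that could be tested, 4 passed with the preset correlation of camera and 0 with an estimated correlation. The list of immune-response miRNAs, which are induced by inflammatory signals in many cell types, was higher with SMARCA4 (camera adjusted p = 0.0193, adjusted p = 0.431 with an estimated correlation). All 7 measured members had a positive log2 fold change, with a median of 1.17. None passed over all miRNAs, and 2 rose when adjusted over the list alone. Its most abundant members were miR-146b-5p, at 237 ± 151 against 603 ± 282, and miR-132-3p, at 307 ± 54.7 against 463 ± 139 (SD, n = 3 each; adjusted p = 0.174 and 0.317). The miR-30 family was lower (camera adjusted p = 0.0194, adjusted p = 0.431 with an estimated correlation), with 7 of 7 members lower, a median log2 fold change of −0.53, 0 members past the threshold over all miRNAs and 2 that fell when adjusted over the list alone. Its most abundant members were miR-30a-5p, at 81521 ± 25253 against 61833 ± 13537, and miR-30d-5p, at 12670 ± 1226 against 8797 ± 870 (SD, n = 3 each; adjusted p = 0.494 and 0.230). Without empty vector replicate 2 the miR-30 list had an adjusted p of 0.0512, and without the mean-variance trend 0.0995. The list of miR-221 and miR-222 arms was lower (camera adjusted p = 0.0377, adjusted p = 0.515 with an estimated correlation). Over all miRNAs 2 of its 4 arms fell, and adjusted over the list alone 3 fell and miR-221-3p rose. That list was chosen because the study names miR-222, so its count is not independent evidence of the direction. Its adjusted p was 0.0772 with libraries rescaled to the same total, 0.0995 without the trend, 0.0516 without empty vector replicate 1, 0.0610 without empty vector replicate 3 and 0.0659 without SMARCA4 replicate 2.

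The let-7/miR-98 family, which represses growth-promoting genes such as RAS and HMGA2, was higher with SMARCA4 by camera (adjusted p = 0.0498, adjusted p = 0.629 with an estimated correlation). All 9 members were higher, with a median log2 fold change of 0.75, but 0 passed over all miRNAs and 0 when adjusted over the list alone. SMARCA4 replicate 2 carried most of this difference. let-7a-5p was at 62643 ± 8767 against 145734 ± 149564, and let-7f-5p at 26896 ± 1060 against 55418 ± 58347 (SD, n = 3 each; adjusted p = 0.481 and 0.635). The 9 members made up 20.9% of the total in SMARCA4 replicate 2 and between 6.54% and 7.78% in the other 5 libraries. Without SMARCA4 replicate 2 the list had an adjusted p of 0.658, with let-7a-5p at a log2 fold change of −0.07 and let-7f-5p at −0.31. The list also missed the threshold without empty vector replicates 1, 2 or 3 (adjusted p = 0.0593, 0.0743 and 0.0778), with quantile normalization (0.140), with array weights (0.328), without the trend (0.12), with a mean of at least 10 (0.0835) and with a pseudocount of 0.5 or 5 (0.0504 and 0.0511). Members of this family differ by few bases, so their separate values depend on how the counting treated near-identical reads.

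**Figure D3:**
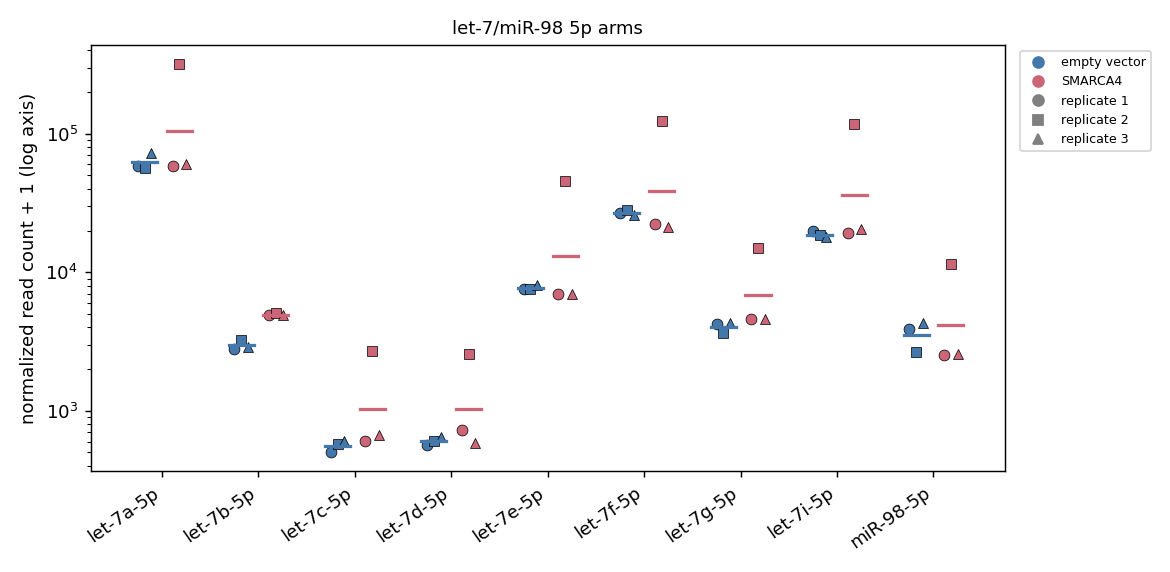
Normalized read count plus 1 (log axis) of the 9 let-7/miR-98 members in each library; points are libraries, shapes are replicates and lines are geometric means of 3 libraries. SMARCA4 replicate 2 is the highest library for all 9 members, and for let-7b-5p the 3 SMARCA4 libraries lie close together.

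The other 13 lists did not pass, and 2 single members of them changed over all miRNAs. In the miR-200 family (adjusted p = 0.243), miR-141-3p rose while the most abundant member, miR-200b-3p, was at 422 ± 123 against 190 ± 51.8 (SD, n = 3 each; limma adjusted p = 0.109). Adjusted over the list alone, 1 of its 7 members rose and 1 fell. miR-141-5p, the other arm of the miR-141 hairpin, did not pass (log2 fold change 0.05, limma adjusted p = 0.972). Neither did miR-200c-3p (−0.06, limma adjusted p = 0.970). Both were scarce, with means of 3.59 and 7.80 over all libraries. In the 14q32 imprinted cluster (adjusted p = 0.230), miR-654-3p fell and the other 25 members did not pass. Adjusted over the list alone 2 fell, while miR-381-3p and miR-411-5p had log2 fold changes of −0.42 and −0.29. The list of hypoxia and metabolic stress miRNAs had an adjusted p of 0.127, 0 members past the threshold over all miRNAs and 4 that rose and 1 that fell when adjusted over the list alone. With a mean of at least 10 required its adjusted p was 0.0447. Its most abundant members, miR-103a-3p and miR-107, had log2 fold changes of 0.21 and 1.24. The miR-29 family, whose targets include collagen genes, had 6 of 6 members lower (adjusted p = 0.127), with miR-29a-3p at −0.27 and miR-29b-3p at −0.61. Leaving out SMARCA4 replicate 3 brought its adjusted p to 0.0450.

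No member passed over all miRNAs in the p53-responsive list (adjusted p = 0.448, miR-192-5p and miR-194-5p at log2 fold changes of 0.43 and 0.06, 1 member fell when adjusted over the list alone) or the miR-17-92 and paralog clusters (adjusted p = 0.658, miR-92a-3p and miR-25-3p at 0.57 and 0.83). The same held for the list of miR-99, miR-100 and miR-125 members (adjusted p = 0.231, miR-125a-5p and miR-100-5p at −0.12 and 0.30) and for the TGF-beta and mesenchymal list (adjusted p = 0.658, miR-21-5p and miR-22-3p at −0.30 and −0.31). In the miR-23/27/24 clusters (adjusted p = 0.658) the median log2 fold change was 0.15 and the test pointed up while the mean was −0.13, with miR-27b-3p at 0.88 and miR-27a-3p at 0.37. In the miR-15/16 family (adjusted p = 0.902) the median was −0.25 while the test pointed up and the mean was 8.03e-04, with miR-16-5p at 0.16 and miR-15b-5p at −0.44. In these 6 lists no other member passed when adjusted over the list alone. The signs of miR-192-5p, miR-194-5p, miR-16-5p, miR-100-5p, miR-103a-3p and miR-128-3p changed under at least 1 other scaling.

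Markers of other cell types and of RNA quality did not pass either. Of the blood cell miRNAs, 3 of 8 were measured (adjusted p = 0.243), with miR-486-5p at 6359 ± 813 against 10094 ± 3752 and miR-142-5p at 21.3 ± 19.7 against 54.9 ± 30.3 (SD, n = 3 each). Of the muscle, liver and neuron miRNAs, 3 of 9 were measured (adjusted p = 0.657), with miR-128-3p at 1387 ± 393 against 1630 ± 182 and miR-9-5p at 143 ± 3.21 against 246 ± 157 (SD, n = 3 each). Of 16 pluripotency and placenta miRNAs, 0 were listed in the table. Of the 13 measured entries that overlap other RNA classes, such as fragments of tRNA, 10 were higher with SMARCA4 (adjusted p = 0.142), with miR-1260b at a log2 fold change of −0.03 and miR-7977 at 0.65. No member of these lists passed over all miRNAs or when adjusted over the list alone.

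None of the 5 most abundant miRNAs, ranked by mean normalized count over all libraries, passed the test. By mean share of the total, miR-22-3p (4.86%) lay above miR-10a-5p (4.78%) and let-7a-5p (4.62%). In normalized counts, miR-21-5p was at 387595 ± 90924 against 323492 ± 124236 (limma adjusted p = 0.645), miR-27b-3p at 165481 ± 17898 against 313047 ± 98453 (0.141), miR-192-5p at 201519 ± 23653 against 271083 ± 29083 (0.381), let-7a-5p at 62643 ± 8767 against 145734 ± 149564 (0.481) and miR-10a-5p at 65725 ± 19824 against 120156 ± 9143 (0.124; SD, n = 3 each). The groups did not overlap for miR-27b-3p, miR-192-5p and miR-10a-5p. As a share of the total they did not overlap for miR-21-5p (19.0% to 27.7% against 13.5% to 15.2%) or miR-27b-3p (8.35% to 11.1% against 13.6% to 14.5%). Not passing does not show that levels were equal, since the test called 20.8% of simulated 2-fold changes when 200 of 637 miRNAs were changed. The 10 most abundant miRNAs together held 68.7% ± 2.62 against 69.1% ± 0.697 (SD, n = 3 each), a difference of 0.402 percentage points (exact two-sided permutation p = 0.9). Without empty vector replicate 3 this difference was −0.703.

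Changes of the 5p and 3p arms were compared next, since both arms of a hairpin come from 1 precursor. Arms were paired by name, so a 5p name that several hairpin genes share met the 3p arm of only some of them. The miR-181a pair was such a case, since miR-181a-2-3p was left out of it. Across 155 hairpins with both arms tested, the log2 fold changes of the arms showed no detectable relation (Spearman rho 0.030, permutation p = 0.709). Hairpins are not independent replicates, and rho was −0.014 over the 97 hairpins whose arms both had a mean of at least 10. miR-222 was a hairpin whose arms both fell, whereas the arms of miR-221 had opposite signs.

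**Figure D4:**
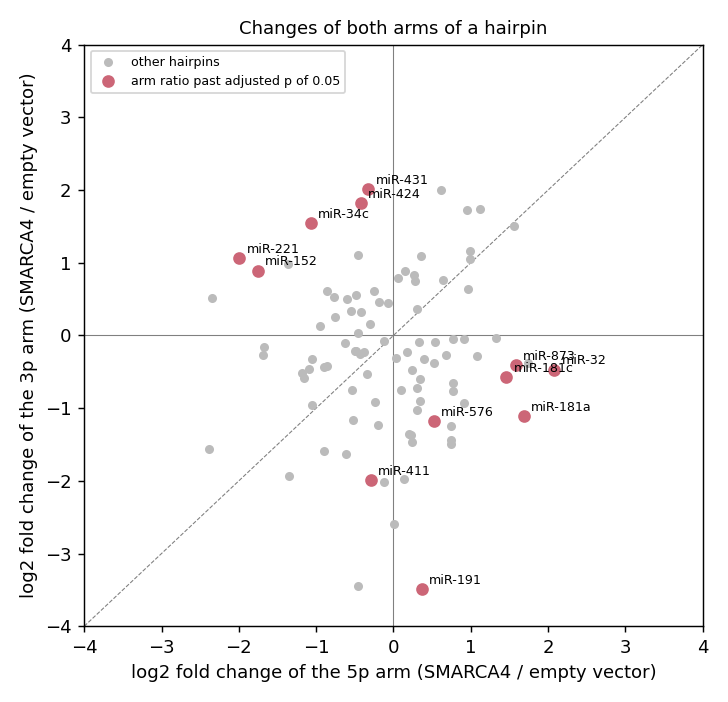
Log2 fold change of the 3p arm against that of the 5p arm for 97 hairpins whose arms both have a mean of at least 10; the dashed line marks equal change. The 12 hairpins in red, whose arm ratio passed an adjusted p of 0.05, lie away from that line, 11 of them with arms of opposite sign. Selection by the ratio favours both features.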

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

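The thinning of SMARCA4 replicate 2 and the arm filter at a mean of at least 100 were chosen after seeing the data. Across the settings that kept all 6 libraries, the 48 named miRNAs other than the arms of miR-221 and miR-222 gave 624 values, of which 575 kept direction and side of the threshold, 7 lost and 30 gained a call and 12 changed sign. miR-222-3p kept its fold but not its call without the trend (log2 fold change −1.57, adjusted p = 0.0695). miR-221-3p passed with array weights (0.82) and DESeq2 (1.12), and miR-221-5p with array weights (−2.03) and DESeq2 (−2.08). Array weights called 90 miRNAs and DESeq2 47, against 9, with all 9 among both. The list count was 1 without the trend and 0 with an estimated correlation, against 4, and the Spearman correlation between arm changes was −0.014 at a mean of at least 10. The cause of these differences was not tested. Changed signs, all of values that did not pass, were as follows. With libraries rescaled to the same total they were miR-194-5p −0.26, miR-16-5p −0.17, miR-100-5p −0.0198, miR-103a-3p −0.12 and miR-128-3p −0.0527. With quantile normalization they were miR-192-5p −0.30, miR-194-5p −0.0739, miR-16-5p −0.14, miR-100-5p −7.89e-04 and miR-103a-3p −0.0624. With array weights they were let-7f-5p −0.0731 and miR-1260b 0.16.

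The replicate numbers paired the libraries weakly if at all, and whether they do was not settled. Correlations of deviations between same-numbered libraries were 0.073, 0.088 and 0.014. Between differently numbered libraries they ranged from −0.095 to 0.049, and 5 of 6 libraries correlated best with their own number. With the replicate number as a block, 13 miRNAs were called, the 9 among them, miR-221-5p passed (−2.00, adjusted p = 0.0227), and the list count stayed at 4.

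Leaving out 1 library in turn gave 0 to 41 changed miRNAs and 2 to 5 lists. The log2 fold change ranged from −1.65 to −1.51 for miR-222-3p, from −2.52 to −2.27 for miR-222-5p, from 0.71 to 1.25 for miR-221-3p and from −2.43 to −1.64 for miR-221-5p. The Spearman correlation between arm changes ranged from −0.0204 to 0.0676, and the difference in the share of the 10 most abundant miRNAs from −0.703 to 1.85 percentage points. Values that changed sign ranged from −0.0682 to 1.16 for let-7a-5p, −0.31 to 0.96 for let-7f-5p, −0.27 to 0.76 for miR-100-5p, −0.0592 to 0.42 for miR-103a-3p, −0.48 to 0.18 for miR-125a-5p, −0.23 to 0.13 for miR-1260b, −0.0877 to 0.29 for miR-16-5p, −0.0694 to 0.22 for miR-194-5p and −0.59 to 0.0534 for miR-29a-3p. Depth limits the scarce miRNAs most, since 3 reads are worth 7.84 normalized counts in SMARCA4 replicate 1. With SMARCA4 replicate 2 thinned to the depth of the others, 9 miRNAs were called, the same 9.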

Other observations

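The list tests and the test of both arms were planned, while the tests of arm ratios, of let-7 in 1 library, of the ratio of miR-221-3p to miR-222-3p and of the immune hypothesis were chosen after the values were seen. Of these, the GC test for let-7, the GC test for arm ratios and the test of weak arms had their outcomes written down before they were run.

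Without SMARCA4 replicate 2, the leave-one-out setting with the most calls (41 miRNAs, 17 rose, 24 fell), 3 of the 5p arms of the miR-181 family rose (miR-181a-5p, miR-181c-5p and miR-181d-5p, log2 fold changes 1.40, 1.45 and 1.00) and 2 of the 3p arms fell (miR-181a-3p and miR-181a-2-3p, −1.29 and −1.17). The miR-181b arms and miR-181c-3p passed in neither setting, and the family as a whole was not tested. miR-181 members are known regulators of lymphocyte signalling and of differentiation. Both arms of miR-324 rose in the same setting (5p 1.49, 3p 1.48), as did miR-10b-5p (1.03) and miR-130a-3p (0.93), while miR-34c-5p (−1.12), miR-148b-3p (−1.28) and miR-30e-5p (−0.76) fell. With all 6 libraries only miR-181c-5p of these passed, and these miRNAs were chosen after their values were seen.

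Over hairpins whose arms both had a mean of at least 10, 12 of 97 changed the log2 ratio of 5p to 3p with SMARCA4 (limma, adjusted p under 0.05, 31 at an unadjusted p under 0.05). Of these, 7 moved toward 5p, among them miR-181a (2.80), miR-32 (2.55) and miR-191 (3.86, a size resting on 0, 18 and 1 reads of its 3p arm with SMARCA4). The other 5 moved toward 3p, among them miR-221 (−3.06) and miR-34c (−2.61). In 11 of the 12 the arms had opposite signs, which selection by the ratio favours, so that count is not a separate result. Among the 32 hairpins with both means of at least 100, 6 passed when adjusted over those 32, of which miR-181a, miR-181c, miR-221 and miR-424 are among the 12 and miR-23a and miR-455 are not, so counting noise in weak arms does not account for these 4 but stays open for the other 8, whose weaker arm had a mean of 10.3 to 54.8. The changes did not follow the GC difference between the 5p and 3p sides of the hairpin gene (rho −0.016 across hairpins). Mature sequences were not used for that difference, so it cannot decide on a GC effect of the arms themselves. What underlies the changed arm ratios was not tested, and differences in ligation or in the authors' counting of arms stay open. The miR-181a pair left out miR-181a-2-3p, so its ratio is not one within 1 precursor.

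miR-221-3p and miR-222-3p come from hairpins in 1 host gene, share a seed and had log2 fold changes of opposite sign, of which only the fall of miR-222-3p passed. Their ratio within a library, which no scaling can change, was 0.315 ± 0.038 in empty vector cells and 2.01 ± 0.689 with SMARCA4 (SD, n = 3 each), a log2 difference of 2.63 with no overlap (exact two-sided permutation p = 0.1, the smallest possible), so scaling between libraries does not account for it. Reads shared between both arms stay open, since the sequences differ at 10 of 21 positions side by side, the distance looked at first, but by only 3 edits with gaps when the last bases of miR-221-3p are not counted, which was put in its place after that count was seen, and by 6 over the full sequences, so the answer depends on how read ends were treated. The aligner is not given in the sources used here, and the sum of both arms depends on the scaling: as deposited it overlapped between groups through SMARCA4 replicate 2 alone (27361 to 32264 against 18293, 32289 and 18922), while as a share of each total it did not (1.54% to 1.83% against 0.997% to 1.05%). Such sharing would leave miR-222-5p untouched, so it would not account for the fall of that arm. The 5p arms decide nothing about the 3p arms, since arm changes showed no detectable relation across hairpins.

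In SMARCA4 replicate 2 the let-7/miR-98 5p arms lay above the mean of the other SMARCA4 libraries by 1.69 to 2.73 log2 units for 8 of 9 members and by 0.06 for let-7b-5p. Scaling of the whole library does not account for this, since all other tested miRNAs had a median deviation of 0.195. The let-7 median was still 2.07 after a trend on GC content was removed. That GC content was taken from the side of the hairpin gene that holds the arm, not from the mature miRNA. The test therefore cannot decide on a GC effect of the mature sequences, which stays open. More let-7 hairpins in that culture cannot be told apart from other causes. The 10 3p arms had a median deviation of −0.039 with an interquartile range of 1.73, which at first seemed to argue against it, but a check added afterwards found that arms of the same hairpin did not deviate together in that library (rho −0.045), so the 3p arms decide nothing. miR-1261 (3.51), miR-320a (3.35), miR-196a-5p (2.78) and miR-196b-5p (2.27) had the highest deviations outside the family among miRNAs with a mean of at least 200 over all libraries, and a different library preparation or sequencing run, for which the labels give no batch, was not tested.

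The rise of miR-3614-5p, whose hairpin lies in a UTR of TRIM25, and the higher values of the immune-response list may reflect an innate response to the plasmids that differs between the groups. The list passed camera with the preset correlation and fry (adjusted p = 0.0193 and 0.0430), and 7 of 7 members were higher. It did not hold in camera with an estimated correlation (adjusted p = 0.431), so the data do not decide.

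With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 9 miRNAs where the highest of the other 9 splits called 0. It gave 4 lists against at most 3, and 12 hairpins with a changed arm ratio against at most 0. In each case 1 of the 10 splits, the real one, reached that count. Every other split mixes both groups on each side, so any difference between the groups adds to the spread there and can lower the count. The counts of those splits therefore do not show what libraries without a group difference would give.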
